A study of Saccharopolyspora erythraea with 4 samples.

How the data were processed

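RNA of a dasR null mutant and of the wild type of S. erythraea, each at 24 h and 48 h, was hybridised to 4 custom 2-colour oligonucleotide arrays on 1 slide, with 2 arrays per time point. Per the labels, RNA was isolated with a column kit, amplified and labelled with a low-input 2-colour protocol, the mutant with Cy3 and the wild type with Cy5 on every array. Per the file headers, spot intensity values in both channels were extracted by the authors with Feature Extraction 10.7.3.1. Per the file headers, the scanner software also gave background-subtracted and dye-normalised processed intensity values. Its log10 values, as deposited and tested on the values, are the log10 ratio of processed Cy5 over processed Cy3 within 0.005, except for 41 gene spots on 24 h replicate 1 and 1 on 48 h replicate 2 that the software set to 0, and they were not used further. The deposited table of log2 values equals the log2 ratio of the processed Cy3 over the processed Cy5 intensity within 0.01 for 100% of gene probes, so its scale and direction are known. Its column medians were 0.0044, -0.0161, -0.0156 and -0.0040.

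Mean foreground and median local background intensities were corrected with normexp (offset 50) and normalised by loess within each array in limma 3.58.1 (R 4.3.3), with the 536 control spots at weight 0 and spots flagged as outliers left out (0 to 3 gene spots per array). No gene spot was saturated. A probe was kept if well above background on both arrays of a time point in at least 1 channel, which kept 14492 of 14498 probes and all 7263 genes, so this filter removed almost nothing. The 2 probes of a gene were averaged (7235 genes had 2 and 28 had 1). The probes of a gene lay beyond 0.5 in opposite directions for 1 gene at 24 h and 3 genes at 48 h. Probes of different genes shared at least 45 consecutive bases for 152 genes, whose values are uncertain. Spike-in controls gave an observed over expected slope of 0.887 to 0.905 for the log ratio, so ratios are somewhat compressed.

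Identifiers of the array were matched to locus tags of assembly ASM6288v1 for 6955 of 7263 genes, of which 829 had a symbol. The genome build behind the array is not given in the sources used here, so no coordinates are printed.

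Log2 ratios of mutant over wild type were fitted with lmFit and eBayes over all 4 arrays with 1 mean per time point, which leaves 2 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all genes. Time changes used a separate-channel fit after Aquantile normalization (intra-spot correlation 0.183) and, chosen after seeing the data, the mutant channels alone. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation. Of 24 lists fixed before the data were examined, 11 had at least 3 genes and 13 had fewer, because the gene table gives symbols and no product names. A further 22 lists were chosen after the gene table was read, from symbols and gene types alone, and 33 were tested. Wild-type list medians over time were set against 10000 random lists drawn within 20 bins of brightness.

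Genes named in the text follow a rule fixed before the data were examined, except where the text says otherwise. It names dasR first, which the gene table lacks, and 1 gene it takes is not reported here. For each comparison it takes the 10 highest rises and 10 lowest falls among genes past an adjusted p of 0.05 with the same direction on both arrays of each time point compared, the 5 of highest moderated t where fewer than 5 pass, and up to 4 members of each list by p. For time changes it takes 5 each way and 2 per list. Members of the erythromycin cluster may all be named.

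The calculations were tested on simulated spots for 7263 genes. Of genes changed 2-fold, 71.6% were called at 24 h, 88.1% at 48 h and 16.4% in the difference, and of genes changed 4-fold, 92.4%, 98.5% and 92.4%. Fitted changes were a median of 0.722 to 0.827 of the simulated ones, and unchanged genes made up 5.6%, 2.17% and 7.6% of the calls in the 3 comparisons. No simulated change was called in the wrong direction. Each simulated gene had the same spread between mutant cultures at both times. In the real mutant channel the replicate difference had an SD over probes of 0.282 at 24 h and 0.469 at 48 h. The simulated shares of changed genes called may therefore not hold for the real arrays. A simulated list of 30 genes shifted by 0.7 was called by camera at the preset correlation and not with an estimated one (adjusted p = 0.204). The simulated wild type carried probe noise but no variation between cultures, and no dye bias of a gene was simulated. False calls from a varying wild type or from a dye bias were therefore not tested. The simulated genes also varied independently, so false calls of lists with correlated genes were not tested. In the real data the estimated correlation was 0.87 for ribosomal proteins.

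Alternatives covered the background correction, the within-array normalization, the filter, the deposited log2 ratios, single probes, each time point alone, the moderation, fold thresholds, the replicate number as a block, and each array left out.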

Results

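Transcript levels were compared between a dasR null mutant of Saccharopolyspora erythraea and its wild-type parent NRRL23338. This actinomycete makes the antibiotic erythromycin, and DasR is a GntR-family transcription regulator. Both strains were grown in TSB, a rich liquid broth, and sampled at 24 h and 48 h. Each of the 4 arrays carried mutant RNA labelled with Cy3 and wild-type RNA labelled with Cy5, with 2 arrays per time point from cultures the labels call independent. The array held 14498 gene probes for 7263 genes. Median spot intensity lay between 151 and 211 in the mutant channel and between 196 and 272 in the wild-type channel, against median local backgrounds of 31 to 34 and 47.5 to 54. The share of gene probes well above background was 85.6% in the mutant channel of 24 h replicate 1 and at least 98.8% in that channel of the other arrays. The number of arrays limits the precision.

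The 2 wild-type hybridisations of each time point nearly coincided. The replicate difference had an SD over probes of 0.109 at 24 h and 0.126 at 48 h in the wild-type channel, and 0.282 and 0.469 in the mutant channel (log2, quantile-normalised). Where 1 gene had a pair of dissimilar probes, their replicate differences correlated at 0.016 and 0.043 in the wild type and at 0.476 and 0.855 in the mutant. The wild type was therefore counted as 1 sample per time point, and the ratio tests rest on the spread between the 2 arrays of a time point, pooled over both times. If 1 wild-type sample was used on both, that spread leaves out the wild type's own. The ± of a ratio is the SE from this pooled and moderated spread, so it is not the spread of the 2 arrays of 1 time alone. No array had the dyes swapped, so a dye bias of a gene remains in each ratio and cancels only in the difference between time points. The targeted gene could not be used as a check of the labels, because the gene table used here names no dasR.

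The comparison at 24 h asks which transcripts differed between the strains at the earlier time. The genes that rose in the mutant included SACE_7297, with a log2 ratio of mutant over wild type of 3.63 ± 0.15 (SE, n = 2 mutant cultures; limma adjusted p = 0.019), and SACE_3579, at 3.59 ± 0.15, but probes of this pair share sequence, so which of them changed is uncertain. SACE_0498 rose by 3.22 ± 0.18 and SACE_7183 by 1.92 ± 0.09. Of the genes that fell, aceA (SACE_1449), named for isocitrate lyase of the glyoxylate shunt, had a log2 ratio of -2.93 ± 0.16 (adjusted p = 0.030). SACE_6912 stood at -2.14 ± 0.07 and SACE_2123 at -1.20 ± 0.07. In all, 8 genes, 5 higher and 3 lower, passed an adjusted p of 0.05 in limma over 7263 genes, while 1785 had an unadjusted p under 0.05. The limma count was 0 without 24 h replicate 1 (1589 unadjusted), 0 without 24 h replicate 2 (444 unadjusted), 686 without either 48 h array, 0 with a trend in the moderation (1891 unadjusted) and 181 with the scanner software's processed signals. It was also 0 (400 unadjusted) when the wild type was assumed to vary like the mutant, an assumption chosen after seeing the data.

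Of 33 gene lists, 7 lay apart from other genes at 24 h by the camera test, although none of their members passed the test over all genes. The 23 genes of the erythromycin cluster had a median log2 ratio of -0.19, with 2 above 0. None passed over all genes and 10 fell when adjusted over the list alone, SACE_0727 at -0.70 ± 0.10 and SACE_0716 at -0.59 ± 0.08 among the lowest. The camera test placed the cluster below other genes (adjusted p = 2.68e-05), a call lost with an estimated correlation (adjusted p = 0.827). The 12 ribosomal RNA genes, which all share probe sequence with other genes and are not independent, had a median of -1.93, SACE_8105 and SACE_8112 both standing at -1.94 ± 0.14 (adjusted p = 0.0503). Their camera adjusted p was 5.51e-12, and 0.827 with an estimated correlation. The 7 mycofactocin genes, which mature a redox cofactor, had a median of -0.85, with mftA (SACE_2387) at -1.30 ± 0.18 and mftC (SACE_2389) at -0.90 ± 0.09. The 17 genes listed as IS21-type transposition genes, 10 of which share probe sequence, had a median of -0.38. By symbol they are istA and istB genes plus tnpA (SACE_2752) and tnpB (SACE_3728). Translation factors (20 genes, median 0.38), ribosomal proteins (56 genes, median 0.25) and DNA repair genes (31 genes, median 0.13) lay above other genes, with the DNA damage repressor gene lexA (SACE_1760) at 0.85 ± 0.11. Camera adjusted p was 2.68e-05, 2.76e-06, 9.74e-04, 0.0336 and 0.0016 for these 5 lists in that order. With an estimated correlation no list was called, with an adjusted p of 0.862 for ribosomal proteins and 0.827 for the others. Ribosomal proteins were no longer called without 24 h replicate 1 (adjusted p = 0.15), without 24 h replicate 2 (adjusted p = 0.079), with processed signals or with median centring, and adjusted over the list alone none of their genes passed.

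The comparison at 48 h asks the same of the later time. Of 7263 genes, 822 rose and 962 fell in the mutant, 1784 in all, of which 148 rose and 126 fell at least 2-fold. Of these, SACE_3204 had the highest ratio, 3.53 ± 0.39 (pooled SE, n = 2, limma adjusted p = 0.014). The neighbours SACE_0917 (3.34 ± 0.18) and SACE_0918 (2.91 ± 0.09) rose together, as did SACE_0756 (2.92 ± 0.14) and rpmF (SACE_0757, 2.78 ± 0.07), named for a protein of the large ribosomal subunit. SACE_0567 rose by 2.91 ± 0.34 and SACE_1895 by 2.82 ± 0.12. The genes that led at 24 h were again high, SACE_7297 at 3.33 ± 0.15, SACE_3579 at 3.32 ± 0.15 and SACE_0498 at 3.08 ± 0.18. The lowest values included transfer RNA genes, with SACE_8038 at -3.49 ± 0.33 and SACE_8037 at -3.45 ± 0.34, which share probe sequence, and SACE_8048 at -3.12 ± 0.41. Other genes that fell were SACE_2475 (-3.15 ± 0.51), SACE_5305 (-3.10 ± 0.07), SACE_5304 (-2.69 ± 0.28), SACE_5148 (-2.62 ± 0.57), SACE_6062 (-2.47 ± 0.27), SACE_6061 (-2.34 ± 0.22) and SACE_1301 (-2.29 ± 0.09). The pooled SE can hide a wide gap at 48 h, as for SACE_2475, at -2.10 on 48 h replicate 1 and -4.20 on 48 h replicate 2. The limma count of 1784 rests on the spread pooled from all 4 arrays, and it was 0 without 24 h replicate 1, 0 without 24 h replicate 2 and 0 from the 48 h arrays alone (2736 with an unadjusted p under 0.05 in each). It was 997 without 48 h replicate 2, 185 by at least 2-fold in both replicates with no test, and 2 (1432 unadjusted) when the wild type was assumed to vary like the mutant.

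Lists of protein synthesis and central metabolism lay above other genes in the mutant at 48 h. Of 56 ribosomal protein genes, 8 rose and 48 did not pass (6 rose when adjusted over the list alone; median 0.90), including rplI (SACE_7348, 2.17 ± 0.30) and rplT (SACE_5279, 1.73 ± 0.19). This list's median was 0.11 on 48 h replicate 1 and 1.78 on 48 h replicate 2, so it rests mostly on 1 culture. Aminoacyl-tRNA synthetases gave 8 rises and 1 fall among 18, with aspS (SACE_2041) at 1.39 ± 0.14 and pheS (SACE_5277) at 1.18 ± 0.07. Amino acid biosynthesis gave 13 rises and 2 falls among 59, nucleotide biosynthesis 8 rises among 25, and translation factors 4 rises among 20. Of the TCA cycle genes 4 of 5 rose, and 5 when adjusted over the list alone, sucD (SACE_6668) by 1.42 ± 0.12 and sucC (SACE_6669) by 1.30 ± 0.15. Glycolysis and pentose phosphate genes gave 6 rises among 19, with gap (SACE_2143) at 1.56 ± 0.20. Of 50 transfer RNA genes 14 rose and 5 fell, and their median was 0.32 despite the deep falls above. The 12 ribosomal RNA genes (median -0.64, 4 fell) and 17 IS21-type genes (median -0.36, 6 fell) lay below other genes. Camera called these 10 lists, with adjusted p from 1.69e-05 for ribosomal proteins to 0.0346 for translation factors. Every one was lost with an estimated correlation (adjusted p = 0.792). Without 48 h replicate 2, 6 were no longer called: ribosomal proteins (adjusted p = 0.451), translation factors (median 0.013, adjusted p = 0.633), transfer RNA genes (adjusted p = 0.361), aminoacyl-tRNA synthetases (adjusted p = 0.12), and nucleotide biosynthesis and ribosomal RNA genes (adjusted p = 0.094 for both). Translation factors were also lost without either 24 h array (adjusted p = 0.064), and ribosomal RNA genes with processed signals (adjusted p = 0.104).

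Genes also changed in lists that camera did not call at 48 h, of which 9 are described here (adjusted p from 0.0934 to 0.774). Over all 7263 genes 822 rose and 962 fell, so members that passed do not by themselves set a list apart, here or above. Of 15 pyruvate and glyoxylate genes 6 rose and 3 fell. Among those that rose were pdhA (SACE_5676, 2.40 ± 0.16) and lpdA (SACE_5677, 1.77 ± 0.16), both named for parts of pyruvate dehydrogenase. The list also holds other genes with these symbols. Of these, pdhA (SACE_7294) did not share the rise, with a log2 signal at 48 h of 9.41 in the mutant and 9.63 in the wild type. Of 14 chaperone and heat shock genes 3 rose and 2 fell (7 and 2 adjusted over the list alone). The chaperonin genes groES (SACE_6715, 2.02 ± 0.40) and groL (SACE_0527, 2.36 ± 0.47) rose, and both clpX genes, named for a subunit of a protease, fell (SACE_1362, -0.79 ± 0.11, and SACE_7334, -0.37 ± 0.07). Of 4 oxidative stress genes 3 rose (3 adjusted over the list alone), including trxA (SACE_7385, 1.03 ± 0.13), and of 3 sigma factor genes 1 rose (1 adjusted over the list alone), sigE (SACE_1037, 1.38 ± 0.29). Of 3 morphological development genes 1 fell, the regulator gene bldD (SACE_2077, -0.91 ± 0.10, limma adjusted p = 0.014), and adjusted over the list alone 1 rose and 1 fell. Of 31 DNA repair genes 1 rose and 8 fell, including recA (SACE_1736, -1.31 ± 0.18). Of 14 cell division and peptidoglycan genes 4 fell (4 adjusted over the list alone), including ftsZ (SACE_5835, -0.79 ± 0.17). Of 23 oxidative phosphorylation genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), the latter cydB (SACE_0143, -1.22 ± 0.12). Of 13 ectoine, trehalose and potassium genes 1 rose and 6 fell, including ehuA (SACE_6266, -1.28 ± 0.15) and otsB (SACE_2447, -1.12 ± 0.10). In the erythromycin cluster none of 23 genes passed at 48 h, over all genes or adjusted over the list alone, and the median was 0.14. Values with a low p were eryCIII (SACE_0726) at 0.34 ± 0.09, SACE_0731 at 0.50 ± 0.15, desII (SACE_0715) at -0.25 ± 0.08 and SACE_0716 at -0.23 ± 0.08. Of the 23 ratios 16 were above 0, and camera did not separate the cluster from other genes (adjusted p = 0.34).

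**Figure D1:**
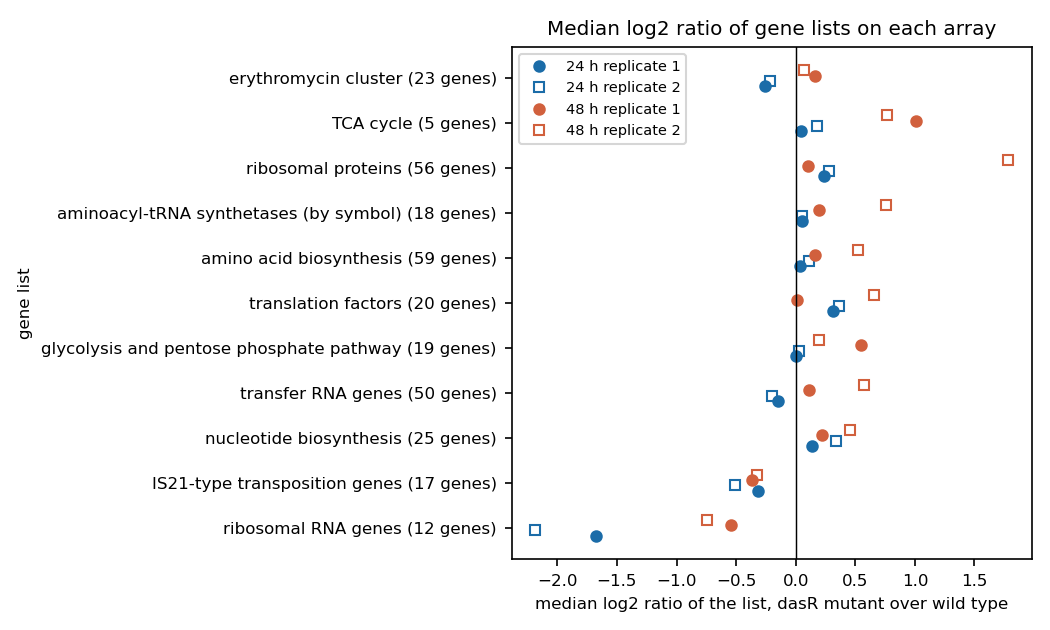
Median log2 ratio of mutant over wild type (x axis) for the 10 lists called at 48 h and the erythromycin cluster (y axis), 1 point per array. Ribosomal proteins stood at 0.11 on 48 h replicate 1 and 1.78 on 48 h replicate 2, and ribosomal RNA genes were below 0 on all 4 arrays.

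The ratio differed between the time points for 446 genes, 236 of them higher at 48 h and 210 lower. This comparison asks which strain differences changed with time. Here a rise or fall is that of the ratio of mutant over wild type, not of the transcript over time. The isocitrate lyase gene aceA rose by 4.05 ± 0.23 (SE of the difference; limma adjusted p = 0.019). Further rises were SACE_3204 (3.51 ± 0.55), SACE_1392 (3.41 ± 0.34), SACE_0756 (3.16 ± 0.20), SACE_7223 (3.07 ± 0.33), SACE_0917 (2.91 ± 0.25), pdhA (SACE_5676, 2.90 ± 0.23), rpmF (2.85 ± 0.10), SACE_0918 (2.72 ± 0.12) and SACE_3766 (2.70 ± 0.35). Transfer RNA genes were among the lowest, SACE_8048 at -5.02 ± 0.58, SACE_8038 at -4.97 ± 0.47 and SACE_8037 at -4.94 ± 0.48. SACE_5305 (-3.04 ± 0.10), SACE_1301 (-2.62 ± 0.12), SACE_5304 (-2.58 ± 0.40) and cydB (-2.25 ± 0.17), named for a cytochrome bd oxidase subunit, followed. In the erythromycin cluster 20 of 23 differences were above 0 (median 0.34), and SACE_0727 (0.88 ± 0.15) and SACE_0717 (0.71 ± 0.12) rose over all genes and 4 when adjusted over the list alone. Camera called this shift (adjusted p = 7.58e-04, and adjusted p = 0.717 with an estimated correlation). The ratios of the methionine synthase gene metE (SACE_4744, 2.34 ± 0.27), the cobaltochelatase gene cobN (SACE_5955, 1.30 ± 0.12) and the glutamate synthase gene gltB (SACE_3998, 1.23 ± 0.10) rose. Those of recA (SACE_1736, -2.08 ± 0.25), lexA (SACE_1760, -1.10 ± 0.15) and bldD (-1.05 ± 0.14) fell. The gltB transcript itself was lower at 48 h in both strains (-1.84 in the wild type and -0.61 in the mutant). That of bldD was higher in both (1.42 and 0.38). The aceA transcript changed by -3.26 in the wild type and 0.79 in the mutant. In the mutant channels alone, the changes of bldD (limma adjusted p = 0.1015) and aceA (limma adjusted p = 0.061) did not pass. Of 13 lists called by camera, none was called with an estimated correlation (adjusted p from 0.717 to 0.811), and ribosomal proteins had a median difference of 0.70 that was -0.27 without 48 h replicate 2. The limma count was 0 without 24 h replicate 1 (1941 unadjusted), 0 without 24 h replicate 2 (1179 unadjusted), 1165 without 48 h replicate 1, 844 without 48 h replicate 2, and 0 when the wild type was assumed to vary like the mutant (803 unadjusted).

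Across all genes the 24 h and 48 h ratios were only loosely related, with Pearson's r = 0.14 and Spearman's rho = 0.16 over genes, which are not independent replicates. Replicate arrays correlated at 0.79 at 24 h and 0.68 at 48 h. Of the genes that passed at both times, 5 were higher in both (0.566 would be shared by independent lists), 1 was lower in both (0.397 by independent lists) and 2, aceA (1.12 ± 0.16 at 48 h) and SACE_2123 (0.42 ± 0.07 at 48 h), changed direction. The gene lower in both was SACE_6912 (-0.66 ± 0.07 at 48 h). The lists of both times rest on the same pooled spread and would share a dye bias of a gene. SACE_7297 and SACE_3579, both among the 5, also share probe sequence. The values for independent lists are therefore no test of the overlap, and a shared dye bias would also add to the correlation. The correlation was 0.065 without 48 h replicate 2. A small set stayed apart on every array, 10 genes at least 2-fold higher and 2 at least 2-fold lower, chosen after their values were seen. Besides SACE_7183, SACE_0498, SACE_3579 and SACE_7297, the higher ones included ptsP (SACE_7368, 3.24 at 24 h and 2.20 at 48 h), named for a phosphotransferase system enzyme of sugar uptake, its neighbour SACE_7367 (1.48 and 1.33), SACE_0497 (1.93 and 1.63), SACE_2061 (1.99 and 1.82) and SACE_2062 (1.84 and 1.46). The lower ones were SACE_0500 (-1.47 and -1.43) and SACE_2475 (-1.37 and -3.15). Of these 7 further genes none passed at 24 h, where ptsP had an adjusted p of 0.0503, and all passed at 48 h.

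Both strains changed broadly between 24 h and 48 h, and the changes of the 2 strains correlated at 0.75 over genes (Spearman's rho 0.73), which are not independent replicates. In the mutant channels alone, 721 genes rose and 582 fell among 1303 past the threshold (2 cultures against 2, limma; 2900 with an unadjusted p under 0.05). SACE_4027 rose by 4.31 ± 0.25 (SE), SACE_5364 by 4.29 ± 0.11, SACE_0619 by 4.15 ± 0.12, SACE_5363 by 4.08 ± 0.58 and SACE_1912 by 3.86 ± 0.20. Of those that fell, SACE_2277 stood at -4.21 ± 0.16, the superoxide dismutase gene sodN (SACE_6419) at -3.96 ± 0.18, SACE_1725 at -3.37 ± 0.30, SACE_2275 at -3.17 ± 0.27 and pfkB (SACE_2273) at -2.96 ± 0.10. The wild type, counted as 1 sample per time point, is described here by fold alone. In it 465 genes were at least 2-fold higher and 568 at least 2-fold lower at 48 h. Its highest changes were SACE_4027 (6.35), SACE_5214 (6.13) and SACE_5747 (5.59), and its lowest SACE_3204 (-5.88), SACE_2277 (-5.12) and sodN (-4.72). Ribosomal proteins had a median change of -2.17 in the wild type and -1.75 in the mutant, amino acid biosynthesis -1.03 and -0.76, and the erythromycin cluster -0.64 and -0.41. The wild-type medians of these 3 lists lay below all of 10000 random lists matched on brightness. So did those of oxidative phosphorylation, aminoacyl-tRNA synthetases, translation factors and nucleotide biosynthesis. The random lists were drawn gene by gene and lack the correlation among genes of a real list, so this is a description and no test. In the mutant 2 of 56 ribosomal protein genes fell and 1 rose, and the list's median against 24 h was -2.67 in 48 h replicate 1 and -0.71 in 48 h replicate 2 (camera adjusted p = 3.49e-06, and adjusted p = 0.727 with an estimated correlation). Of 59 amino acid biosynthesis genes 11 fell in the mutant (camera adjusted p = 5.27e-07, and adjusted p = 0.585 with an estimated correlation). In the mutant, camera placed the erythromycin cluster lower with time (8 of 23 fell; adjusted p = 3.58e-04, and adjusted p = 0.585 with an estimated correlation). With no normalization between arrays the cluster's median was -0.44 in the wild type and -0.13 in the mutant, where the median of all genes moved by 0.25 and 0.26. The planned fit over all channels, which takes hybridisations as replicates, gave 3713 genes in the wild type (1939 up, 1774 down) and 3566 in the mutant (1717 up, 1849 down). With no normalization between arrays the split was 2742 up and 1080 down in the wild type and 2590 up and 988 down in the mutant. The mutant count was 1394 without 24 h replicate 2, and the wild-type count was 2126 without 24 h replicate 1 and 2145 without 24 h replicate 2.

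**Figure D2:**
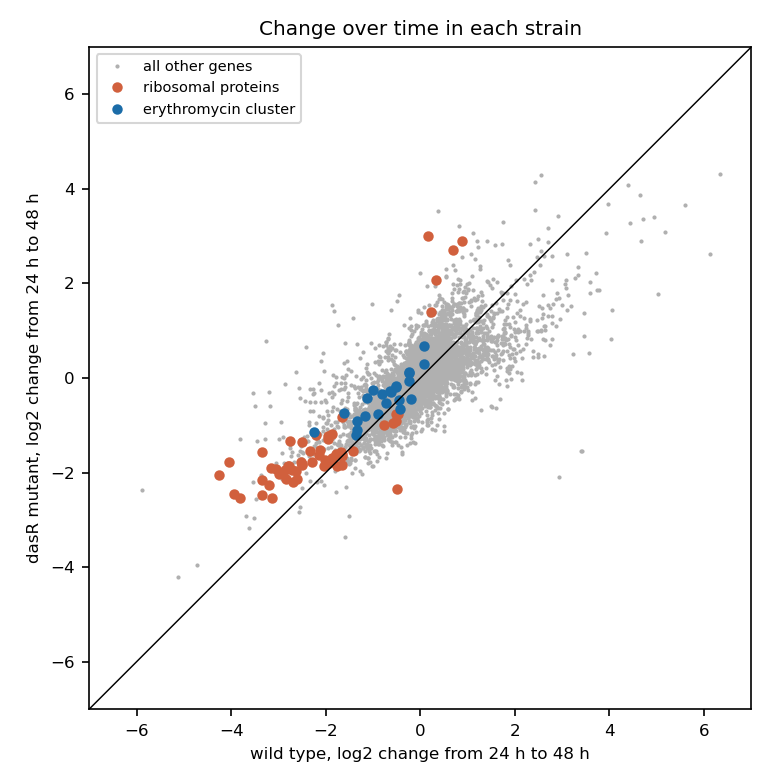
Log2 change from 24 h to 48 h in the wild type (x axis) and in the dasR mutant (y axis), 1 point per gene, with ribosomal proteins and the erythromycin cluster in colour and a line of equal change. Ribosomal proteins had medians of -2.17 in the wild type and -1.75 in the mutant, where 3 of 56 passed the test and the median was -2.67 in 48 h replicate 1 and -0.71 in 48 h replicate 2.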

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

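The tests of the wild-type hybridisations were chosen after the result was seen, and the other tests below before their results were seen.

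The ratio of mutant over wild type differed between 48 h and 24 h for 446 genes by the test of the difference itself. Higher at 48 h were aceA (4.05), SACE_3204 (3.51), SACE_1392 (3.41), SACE_0756 (3.16), SACE_7223 (3.07), SACE_0917 (2.91), pdhA (2.90), rpmF (2.85), SACE_0918 (2.72) and SACE_3766 (2.70). Lower at 48 h were SACE_8048 (-5.02), SACE_8038 (-4.97), SACE_8037 (-4.94), SACE_5305 (-3.04), SACE_1301 (-2.62), SACE_5304 (-2.58), cydB (-2.25), SACE_0232 (-2.19), SACE_0314 (-2.14) and SACE_0441 (-2.14). Among lists, the median difference was 1.25 for ribosomal RNA genes, 0.93 for the TCA cycle, 0.87 for oxidative stress genes, 0.70 for ribosomal proteins, 0.67 for mycofactocin genes, 0.58 for aminoacyl-tRNA synthetases, 0.52 for glycolysis and the pentose phosphate pathway, 0.49 for oxidative phosphorylation and 0.49 for transfer RNA genes. It was 0.34 for the erythromycin cluster, 0.28 for amino acid biosynthesis, -0.17 for DNA repair and -0.45 for cell division and peptidoglycan genes. With an estimated correlation none of these lists was called (adjusted p from 0.717 to 0.811). Ribosomal proteins, aminoacyl-tRNA synthetases, amino acid biosynthesis, glycolysis and mycofactocin genes were no longer called without 24 h replicate 1 (adjusted p from 0.0541 to 0.18). Mycofactocin genes were lost without 24 h replicate 2 (adjusted p = 0.071). Without 48 h replicate 2, transfer RNA genes, aminoacyl-tRNA synthetases and amino acid biosynthesis were lost (adjusted p from 0.0948 to 0.189), and ribosomal proteins had a median of -0.27.

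The first pattern is that the 2 wild-type hybridisations of each time point coincided. Noise in the Cy5 channel large enough to hide differences of the mutant's size is argued against, since the SD of the replicate difference in Cy5 was at most 0.386 of that in Cy3. Smaller differences between wild-type cultures could still be hidden. A single wild-type RNA sample on both arrays of a time point stays open and is consistent with the correlation of at most 0.043 between dissimilar probes of a gene. Wild-type cultures that were pooled or truly alike would give the same values. No biological explanation was tested.

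The second pattern is that ratios at 48 h ran opposite to the wild-type change over time (r = -0.64 over genes). Of 568 genes at least 2-fold lower with time in the wild type, 539 had a ratio above 0 at 48 h, and of 465 at least 2-fold higher, 399 had a ratio below 0. Removing a trend with spot brightness left r at -0.636, against -0.639 before. Loess had already taken such a trend out of the ratios on each array, so this test cannot decide whether brightness plays a part. The wild-type 48 h channel enters both quantities. A test with no shared hybridisation set the ratio of 1 replicate against the mutant's own time change in the other, a different axis, and gave 0.032 and -0.41, so this source cannot be told apart. An earlier growth stage of the mutant cultures at 48 h stays a hypothesis. The 2 mutant cultures differed along the wild-type time change (r = -0.437 for replicate 2 minus replicate 1, and -0.235 at 24 h). This shows a difference between the mutant cultures and cannot show that either lagged behind the wild type. The slope of the 48 h ratio on the wild-type change was -0.264 in replicate 1 and -0.502 in replicate 2.

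The third pattern is the lower ribosomal RNA signal in the mutant at 24 h. Loess at the bright end is argued against, since the median was -1.97 with median centring alone. Compression at the brightest spots cannot be told apart, because only 4 ribosomal RNA genes were dimmer than all of the 50 brightest other genes and their median of -0.93 lay between the values set beforehand. The dimmer genes include SACE_8108 and SACE_8109, which carry the symbol rrf, unlike the bright SACE_8105 and SACE_8112. They may thus stand for a different ribosomal RNA, which also keeps this test from deciding. The 50 brightest other genes had a median of -0.06. Differences in ribosomal RNA content between RNA preparations or between strains were not tested.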

How the results depend on the processing

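Counting the wild type as 1 sample that varies like the mutant, and the mutant channels alone, were chosen after seeing the data. The 24 h count of 8 was 55 with a normexp offset of 16, 181 with processed signals or the deposited ratios, 23 with median centring, 30 with probes above background in both channels of all arrays, 30 by single probes, 686 from the 24 h arrays alone, 0 with a trend in the moderation, 47 by 2-fold in both replicates with no test, 16 with the replicate block and 0 with a varying wild type. The 48 h count of 1784 was 0 from the 48 h arrays alone, 185 by 2-fold in both replicates, 274 when 2-fold was also required and 2 with a varying wild type. The count of 446 for the difference was 278 with no background correction, 281 with median centring, 192 by 2-fold in all pairs, 239 when 2-fold was also required, 19 with the replicate block and 0 with a varying wild type. The lists called, 7 at 24 h, 10 at 48 h and 13 in the difference, were 0 with an estimated correlation. The mutant time count of 3566 was 1303 in mutant channels alone. Leaving out 1 array gave 0 to 686 genes at 24 h, 0 to 1694 at 48 h, 0 to 1165 in the difference, 2126 to 3090 over time in the wild type, 1394 to 3391 in the mutant (both at the 4-array intra-spot correlation), 8 to 11, 5 to 16 and 8 to 19 lists, and r from 0.065 to 0.186. A lone array was assumed to vary like the other time point. The ribosomal protein median of the difference ran from -0.27 without 48 h replicate 2 to 1.57 without 48 h replicate 1. Of 164 gene results, 32 were no longer past the threshold with a trend, 27 with median centring, 24 with no background correction, 54 with the replicate block, 6 with processed signals, 1 with a normexp offset of 16, 1 with the filter on all arrays, 160 with a varying wild type, 162 without either 24 h array, 12 without 48 h replicate 1 and 33 without 48 h replicate 2, and no direction changed. Low signal over background on 24 h replicate 1 limits dim genes. The cause was not tested. Same-numbered arrays deviated together with r = 0.10 over genes, and with only 2 pairs the numbers are not taken as pairs. The slide as a block was not run because all arrays lay on 1 slide. The filter alternative with no filter left the 3 counts at 8, 1784 and 446.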

Other observations

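The test of neighbouring genes was chosen before its result was seen, and the gene runs were named after theirs was.

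Values of 3 smaller gene lists between 24 h and 48 h follow. In the mutant, 13 of 17 IS21-type transposition genes rose, 10 of the 17 sharing probe sequence with other genes (median 0.91, and 1.20 in the wild type). The camera adjusted p was 3.12e-07, and 0.585 with an estimated correlation. Haem synthesis genes had a median of -1.28 in the mutant, where 4 of 6 fell, and -1.15 in the wild type (camera adjusted p = 0.0014 in the mutant, and 0.585 with an estimated correlation). Of 13 genes of ectoine, trehalose and potassium functions 6 rose and 7 did not pass in the mutant (median 0.39), a list camera did not call (adjusted p = 0.07). With no normalization between arrays the mutant medians of these 3 lists were 0.95, -1.28 and 0.48. At 48 h ehuA, ehuD, ehuC and ehuB (SACE_6266 to SACE_6269), named for ectoine uptake, were all lower in the mutant than in the wild type and past the limma threshold, with log2 ratios from -1.28 to -0.36.

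At 48 h, genes past the threshold lay next to each other more often than in shuffled gene orders. Of 7059 pairs with consecutive locus tags, 451 passed in the same direction at 48 h, against a mean of 212 and a highest of 257 over 1000 shuffled orders, which is consistent with transcripts that span neighbours. At 24 h there was 1 such pair, against a mean of 0.006 and a highest of 1 in shuffled orders. The difference between times had 90, against a mean of 12.6 and a highest of 25. There were 37 runs of at least 4 genes at 48 h, against at most 9 in shuffled orders. The longest, SACE_1124 to SACE_1130, held 7 genes that rose (median 0.54). SACE_0756 to SACE_0760 rose with a median of 2.15, SACE_1392 to SACE_1396 with 1.82, and SACE_5674 to SACE_5677, which holds pdhA and lpdA, with 1.70. SACE_6060 to SACE_6065 fell with a median of -1.17. Strand and operon structure were not examined.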
